A study of Homo sapiens with 6 samples.

How the data were processed

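The 6 samples were HTR8 cells harvested 48 h after transfection with a control siRNA (3 arrays) or an siRNA against PRDX2 (3 arrays), each at 100 nmol/L with Oligofectamine. Total RNA labelled with Cy3 was hybridized to Agilent SurePrint G3 Human Gene Expression v3 arrays. The authors deposited one scanner file per array, made with Agilent Feature Extraction 10.7.1.1 as their processing notes and the file headers state. Per the file headers the processed signal is a fluorescence intensity, background-subtracted and detrended within the array, with a small positive substitute value where the spot does not exceed background, and it is not scaled between arrays. The deposited value table of the series holds log2 values whose columns have identical quantiles, with a median of 3.24 in each, so it had been quantile normalized. Its tool is not stated, and it served only as an alternative.

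Control spots and spots with outlier flags were left out, and the spots of one probe were averaged on the log2 scale. Each array holds 62976 spots, 60901 of them to RNA targets, from 58201 probes. The value analysed was log2 of the processed signal minus the array's 75th percentile of that value. Probes were kept if flagged well above background on all 3 arrays of at least 1 group. For each gene the kept probe with the highest mean over the 6 arrays was used, which left 20373 genes and transcripts, 15202 of them under a name in the reference table. Probe names were updated through a table of GRCh38.p14 gene names, by RefSeq accession for 31104 probes, by current symbol for 3366 and by an older symbol for 496, and 23235 kept the name in the file. That table served for names alone, and probe coordinates are those of the files, in hg19.

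Groups were compared with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8), with group as the one term, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. With 3 arrays a side, the number of arrays limits the precision. A change is PRDX2 siRNA minus control siRNA in log2 units. Where no array of the dimmer group was well above background, the change is given as a bound, against the lowest signal well above background. Gene lists with at least 5 measured members were tested with camera at a preset correlation of 0.01. Beside it stand camera with an estimated correlation, fry and the numbers of members higher and lower, with p adjusted over all genes and adjusted over the list alone. The test, the filter, the probe rule, the gene lists, the rule for named genes and all alternatives except those said to be added were fixed before the data were examined.

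The 37 lists covered the peroxiredoxin family, thioredoxin, glutathione and peroxide-removing enzymes, NRF2 targets, p53 targets, G1/S and DNA replication, G2/M and mitosis, apoptosis machinery, ATF4 and integrated stress response, endoplasmic reticulum chaperones, cytosolic heat shock genes, metallothioneins, interferon-stimulated genes, NF-kB cytokines, immediate early genes, glycolysis, hypoxia targets, respiratory chain, cholesterol synthesis, fatty acid synthesis, ferroptosis, autophagy and lysosome, matrix metalloproteinases and plasminogen system, integrins and adhesion, collagens and matrix, epithelial-mesenchymal transition, TGF-beta targets, YAP/TAZ targets, Wnt targets, histones, ribosomal proteins and the small RNA pathway. Markers of extravillous trophoblast, villous cytotrophoblast, syncytiotrophoblast, stromal, endothelial and immune cells made up the rest. Some genes stand on more than one list. The listed symbols FSP1 and SARS were left out after the lists were fixed, because the name table gives each as an older name of more than one gene. The intended genes, AIFM2 and SARS1, are on the lists under those names. Named genes were the peroxiredoxins, the 12 largest rises and 12 largest falls among changed genes with non-overlapping groups and a gene symbol, and up to 4 members of each list with the smallest adjusted p. List members that went against their list's direction, IFIT5, SAMD9L, RELB, ICAM1, IL32, CCN1 and RBMS3, were named after their values were seen. Genes on the Y chromosome and XIST were left out of the named genes, and where measured they stayed in the tests and counts.

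On simulated data with the same design, 64 of 100 genes changed 2-fold and 90 of 100 changed 4-fold were recovered, and 9 of 163 calls were false (5.52%). The simulation changed 200 of 20368 genes and drew genes independently, whereas 38.3% of genes were called in the real data. These shares therefore need not hold for the real comparison. A list of 30 genes shifted by 0.5 was called and 0 unshifted lists were. Divisions of the real arrays other than the real groups, given at the end, called 1 to 7 lists. Each of those divisions has unequal numbers of the 2 groups on its sides, so its calls may hold part of the real difference. Neither these counts nor the simulated 0 gives the rate of false list calls on these arrays. Alternatives were normexp background correction (offset 50), quantile normalization, centring on the median, no scaling, no filter or a stricter filter, the mean of a gene's probes or every probe alone, the deposited value table, eBayes with trend and robust options, array weights, treat against a 1.2-fold change, a replicate block, the slide as a block, and leaving out each array. Added after the data were seen were the 75th percentile over probes above background on all 6 arrays, removal of the trend on probe GC content and a search of probe sequences for the siRNA's seed word. A search of 3′ untranslated regions for seed matches was planned and not run, because no sequence of them was at hand.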

Results

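HTR8 cells, an immortalized line from human extravillous trophoblast (the placental cells that invade the uterine wall), were profiled on 6 one-colour Agilent arrays, 3 after transfection with a control siRNA and 3 with an siRNA against PRDX2. PRDX2 encodes peroxiredoxin 2, a cytosolic enzyme that reduces hydrogen peroxide. RNA was taken 48 h after transfection at 100 nmol/L, from 3 independent experiments. Each array carried 58201 probes to RNA targets, of which 45.5% to 49.6% gave a signal well above background, with no saturated spot. The number of arrays limits the precision. The 75th percentile of log2 signal was 8.21, 8.32 and 8.11 on the control arrays and 7.92, 7.86 and 7.81 on the PRDX2 siRNA arrays, so all 3 control arrays were the brighter ones before scaling. Control siRNA replicate 1 lay alone on one slide and the other 5 arrays on a second, called the shared slide here. In a principal component analysis the first component held 68.8% of the variance and separated the groups. The next held 16.0%, with control siRNA replicate 1 at 39.3, the other controls at -22.2 and -28.8, and the PRDX2 siRNA arrays between 1.72 and 8.22.

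The comparison of PRDX2 siRNA with control siRNA asks which transcripts change after transfection with the PRDX2 siRNA in this trophoblast line. A single siRNA sequence is given for PRDX2, and the arrays read RNA and not protein. The changes therefore cannot be assigned to loss of peroxiredoxin 2 alone. PRDX2 mRNA fell to 53.4% of the control level, and PRDX1, its close cytosolic relative, fell with it. The largest changes were not in antioxidant enzymes. Transcripts of the inducible heat shock genes HSPA6 and HSPA1B were among the largest rises, while TXNIP, the inhibitor of thioredoxin, its relative ARRDC4, the cytokine gene IL6 and the endothelin gene EDN1 were among the deepest falls. Among gene groups, interferon-stimulated genes, chaperones of the endoplasmic reticulum, metallothioneins and ribosomal protein genes rose, and histone genes, YAP/TAZ targets, DNA replication genes and cytokine genes fell. None of these 8 groups passed when the correlation between genes was estimated from the arrays (adjusted p = 0.514 to 0.799). For interferon-stimulated genes that loss came without a higher correlation than the preset one. The metallothionein call was lost without any one of 4 arrays. The ribosomal protein rise was not kept with quantile normalization, and without scaling the medians of the ribosomal protein and endoplasmic reticulum chaperone lists lay below 0.

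PRDX2 was read by one 60-base probe at hg19 chromosome 19, 12911978 to 12912037. Its log2 signal relative to the array's 75th percentile was 2.401 ± 0.035 (SD, n = 3) on control arrays and 1.495 ± 0.092 (SD, n = 3) on PRDX2 siRNA arrays. The difference was -0.91 (SE 0.08, limma with Benjamini-Hochberg adjusted p = 7.6e-04), and -0.89 on the shared slide (adjusted p = 0.0016). PRDX1 changed by -0.64 (adjusted p = 0.00231) and by -0.61 on the shared slide. The mitochondrial PRDX3 and the secretory pathway member PRDX4 had values of -0.13 and -0.08, and PRDX5 and PRDX6 of 0.22 and 0.26, none of which passed. Without scaling of the arrays PRDX3 and PRDX4 passed as lower, at -0.48 and -0.43, and with quantile normalization PRDX5 passed as higher, at 0.26. A dimmer PRDX4 probe, above background on 3 control arrays and 1 of 3 PRDX2 siRNA arrays, read -0.86 and passed (adjusted p = 0.034). As a list the family had 2 members lower of 6 and did not pass camera, limma's test of a gene list against all other genes (adjusted p = 0.54, 0.556 on the shared slide). Adjusted over the list alone, 2 fell and 1 rose.

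**Figure D1:**
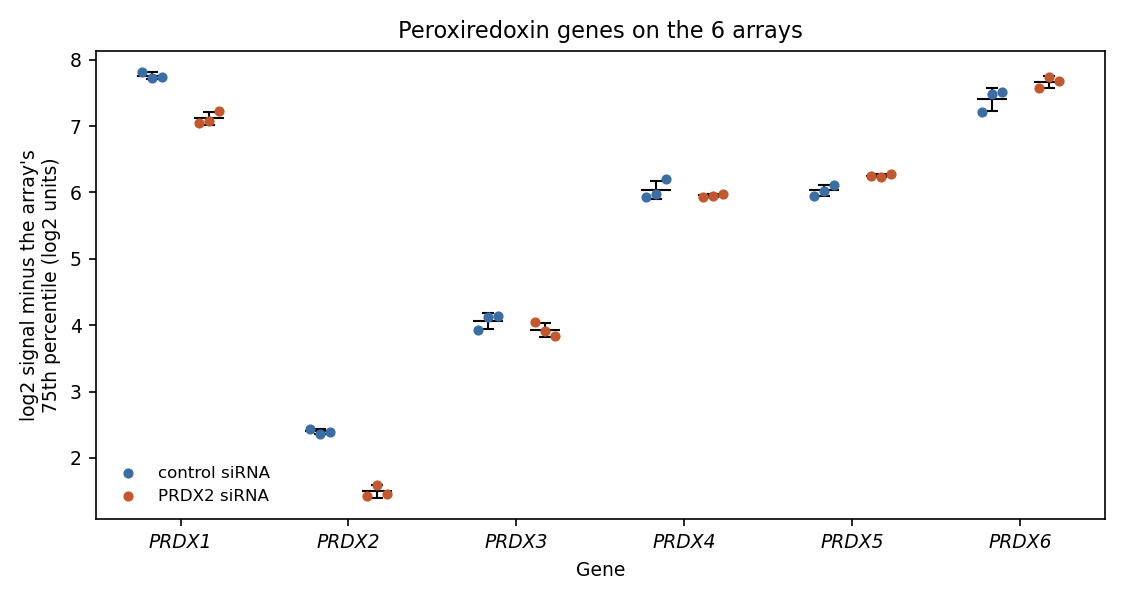
Log2 signal minus the array's 75th percentile (log2 units) of the 6 peroxiredoxin genes on each array, with dots for arrays and black marks for the mean and SD of 3 arrays. PRDX1 and PRDX2 lay lower on every PRDX2 siRNA array than on any control array, with differences of -0.64 and -0.91.

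Of 20373 genes and transcripts tested, 7800 changed (38.3%, limma with Benjamini-Hochberg adjusted p below 0.05), 3647 higher and 4153 lower. The balance depended on the scaling, with 1152 higher and 8413 lower without it, and 5030 and 3395 when the 75th percentile was taken over probes above background on all 6 arrays. Of the 7800, 1682 changed at least 2-fold, 764 higher and 918 lower. The shared slide alone, with 2 control arrays, gave 8501 changed genes, and 7244 of the 7800 changed there in the same direction. The groups did not overlap in 11356 genes (55.7%, against a chance share of 10%). PRDX2 itself ranked 1111 among the falls, so 1110 genes fell further than the siRNA's target.

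The 12 largest rises and 12 largest falls were ranked by fitted change, and where a bound is given the rank itself is not established. Among the rises, HSPA6, a strictly stress-inducible HSP70 gene, went from background on all 3 control arrays to a clear signal, at least 81.9-fold higher (at least 49.1-fold without PRDX2 siRNA replicate 2), and a probe of the same gene measured on all arrays rose by 2.29 on the log2 scale. HSPA1B, the inducible HSP70 itself, rose by 3.56 (SE 0.59, adjusted p = 0.00603, 3.60 on the shared slide, 2.86 without PRDX2 siRNA replicate 2). GAL3ST1, the sulfotransferase of sulfatide synthesis, rose at least 9.14-fold, HHIPL1 at least 3.10-fold and CCDC179 at least 3.65-fold (2.32-fold without PRDX2 siRNA replicate 2), each with 0 of 3 control arrays above background. NGFR, the low-affinity neurotrophin receptor, rose by 3.32 (3.13 on the shared slide) and the epithelial envelope gene SPRR2A by 3.21 (2.74 there), both above background on 2 of 3 control arrays. SPRR2A stood at -0.15 on PRDX2 siRNA replicate 2, against -2.78 and -2.27 on the other PRDX2 siRNA arrays. SHROOM3, an actin regulator of cell shape, rose by 3.24 (2.60 on that slide), TTLL2 by 3.15 (2.503) and CYP7A1, the rate-limiting enzyme of bile acid synthesis, by 3.05 (3.02), each above background on 1 of 3 control arrays, so that the size of these rises rests on control signals not told from background. ESPNL rose by 3.09, and its other probe by 0.88. A probe named for a copy of ribosomal RNA, RNA5-8SN5, rose by 3.25. Such copies are nearly identical in sequence.

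Among the falls, ARRDC4, an arrestin-domain gene controlled like TXNIP by glucose-sensing factors, changed by -4.70 (SE 0.19, adjusted p = 2.0e-04) and by -4.83 on the shared slide. TXNIP changed by -3.67 (SE 0.34, adjusted p = 9.1e-04) and by -3.75 on that slide. IL6 changed by -4.13 (SE 0.17, adjusted p = 2.0e-04) and by -4.30 on that slide, and its other probe also passed as lower, with 0 of 3 PRDX2 siRNA arrays above background. EDN1, the precursor of the vasoconstrictor endothelin, changed by -3.41, and HBEGF, a ligand of the EGF receptor, by -3.18. The linker histone gene H1-1 changed by -3.15, FILIP1L by -3.04 and TIMM13, a chaperone of mitochondrial protein import, by -3.04. KRTAP4-9, a keratin-associated protein gene, fell at least 19.8-fold, the homeobox gene DRGX at least 5.45-fold, and the antisense RNAs STARD13-AS and LPP-AS2 at least 3.72-fold and 3.45-fold, each with 0 of 3 PRDX2 siRNA arrays above background.

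**Figure D2:**
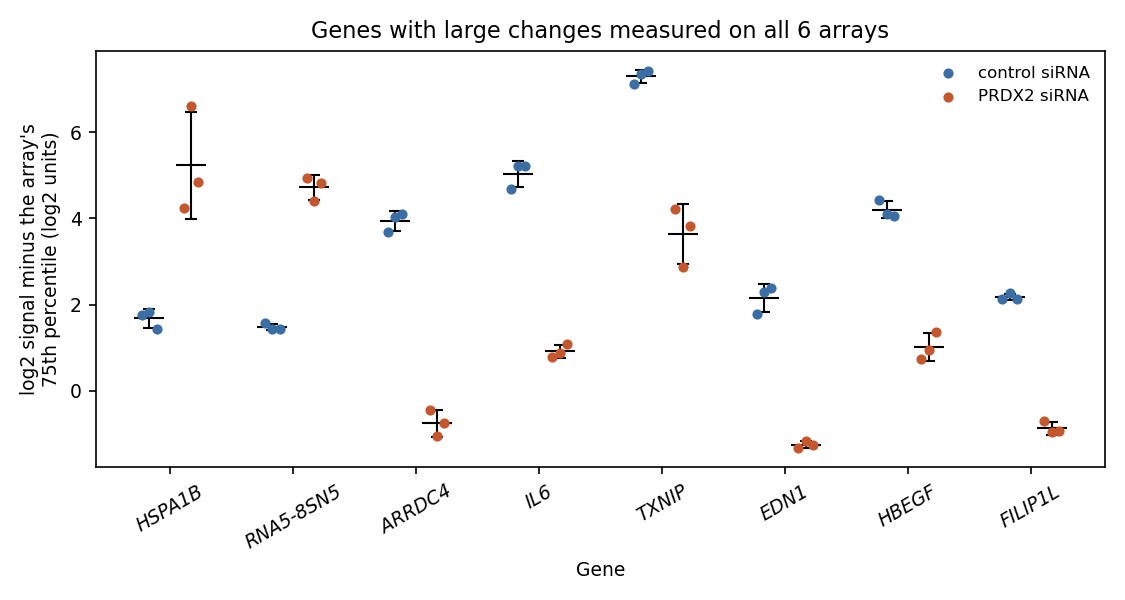
Log2 signal minus the array's 75th percentile (log2 units) of 8 genes measured above background on all 6 arrays, with dots for arrays and black marks for the mean and SD of 3 arrays. HSPA1B and RNA5-8SN5 lay higher on all 3 PRDX2 siRNA arrays, by 3.56 and 3.25, and the other genes lower, down to -4.70 for ARRDC4.

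Of 37 gene lists tested with camera at its preset correlation of 0.01, 8 passed at an adjusted p below 0.05, 4 upward and 4 downward, and 7 of them passed on the shared slide. None passed when the correlation between genes was estimated from these arrays, where 2 had an unadjusted p below 0.05 and the lowest adjusted p was 0.514. For interferon-stimulated genes the estimate was 0.0102, near the preset 0.01, yet camera's unadjusted p went from 2.8e-05 to 0.0139. A higher correlation therefore does not account for the loss of that call. Estimates for the other called lists ran from 0.027 for endoplasmic reticulum chaperones to 0.778 for ribosomal proteins. By fry, which asks whether a list's genes move one way without comparing them with other genes, 21 passed. The counts of single genes depended on the arrays. Summed over the lists, with a gene counted once per list, 196 were higher and 226 lower, and with single arrays left out 143 to 226 and 171 to 233. In 9 lists, none called by camera, the signs differed. The median was above 0 and the mean below 0 in thioredoxin and glutathione enzymes (0.0932 and -0.0787), G2/M (0.0235 and -0.00502), hypoxia targets (0.143 and -0.0275), stromal markers (0.0443 and -0.0294) and endothelial markers (0.211 and -0.194), and the reverse held in apoptosis machinery (-0.0693 and 0.00782) and glycolysis (-0.064 and 0.0313). Camera took the sign of the median in all of these, and fry did too except for endothelial markers. For cholesterol synthesis fry pointed down against a median of 0.0283 and a mean of 0.0741, and for the epithelial-mesenchymal transition camera and fry pointed down against a median of 0.0218. Each gene below is given by its brightest probe, and another probe did not pass for ATF3 (-0.101), BCL2L11 (0.183), GSR (0.223), HSP90AA1 (0.546), LPIN1 (-0.24), LSS (-0.176), MYC (0 of 3 PRDX2 siRNA arrays above background), RPL28 (0.331), SAMD9L (-0.446), SAT1 (0.00497) and XPO5 (-0.231), besides the genes where that is said in place.

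Antioxidant genes moved in both directions. Among enzymes of the thioredoxin, glutathione and peroxide-removing systems 5 of 27 measured genes rose and 5 fell (5 and 7 adjusted over the list alone, 5 and 8 on the shared slide). Here TXNIP fell, as did the methionine sulfoxide reductases MSRB1 (-0.67) and MSRA (-0.73), while GPX8, an endoplasmic reticulum peroxidase, rose by 0.58. The other GPX8 probe read -0.12 and did not pass. Among NRF2 targets 2 rose and 6 fell of 29 measured (2 and 5 adjusted over the list alone, 4 and 6 on the shared slide, 1 to 4 and 3 to 6 with single arrays left out). The cystine transporter SLC7A11 changed by -1.07 and the glutathione conjugate pump ABCC1 by -0.48, and glutathione reductase, GSR, rose by 0.44. HMOX1, on the same list and named after its values were seen, was at 1.58 and did not pass (limma adjusted p = 0.0802). Without PRDX2 siRNA replicate 2 it passed, at 0.88 (limma adjusted p = 0.0244). SLC7A11 and PTGS2 were also among the falls of the ferroptosis-related list, where 3 rose and 9 fell of 23 measured (4 and 9 adjusted over the list alone, 4 and 8 on the shared slide, 2 to 4 and 4 to 8 with single arrays left out). On that list the polyamine enzyme SAT1 rose by 0.87 and the iron regulator IREB2 changed by -0.56. None of these lists passed camera (adjusted p = 0.828, 0.836 and 0.4).

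Chaperones of the endoplasmic reticulum and other unfolded protein response genes rose as a group, with 14 of 28 measured genes higher and 1 lower (15 and 1 adjusted over the list alone, 16 and 1 on the shared slide). The list's median log2 change was 0.32 (camera adjusted p = 0.00214, 6.8e-04 on the shared slide), and adjusted p = 0.547 with an estimated correlation. Without scaling of the arrays, which moved the median of all genes from 0.06 to -0.29, the list's median was -0.03 with 6 genes higher and 6 lower, and it still passed relative to other genes. DNAJB9, a co-chaperone of endoplasmic reticulum HSP70, rose by 1.39, HERPUD1, a factor of protein degradation from that organelle, by 0.93, MANF by 0.88 and the disulfide isomerase PDIA4 by 0.57. In the ATF4 and integrated stress response list 12 rose and 7 fell of 34 measured (13 and 9 adjusted over the list alone, 12 and 9 on the shared slide), and the list did not pass (camera adjusted p = 0.632). DDIT3, which encodes the transcription factor CHOP, rose by 1.08, TRIB3 by 1.097 and the lipoprotein receptor VLDLR by 1.56, whereas ATF3 changed by -1.12. Among cytosolic heat shock genes 5 rose and 1 fell of 20 measured (5 and 1 adjusted over the list alone, 5 and 1 on the shared slide, camera adjusted p = 0.632). Besides HSPA1B, HSPA2 rose by 0.99, HSPA4L by 0.45 and HSP90AA1 by 0.60, the last at 0.22 and not past the threshold with quantile normalization.

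Metallothioneins, small metal-binding proteins, had 5 of 7 measured genes higher and 0 lower (5 and 0 adjusted over the list alone, 5 and 0 on the shared slide), with MT1E at 0.55, MT2A at 0.49, MT1B at 0.47 and MT1A at 0.42. The list's median was 0.47 (camera adjusted p = 0.0496), and adjusted p = 0.799 with an estimated correlation. The call was lost on the shared slide, which leaves out control siRNA replicate 1 (median 0.42, adjusted p = 0.0782), and without control siRNA replicate 2 (0.41 and 0.0532), PRDX2 siRNA replicate 1 (0.45 and 0.0598) or PRDX2 siRNA replicate 2 (0.45 and 0.07). It was also lost without scaling, where 0 genes were higher and 1 lower (0.12 and 0.0872).

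Interferon-stimulated genes rose, with 19 of 32 measured genes higher and 2 lower (21 and 2 adjusted over the list alone, 20 and 2 on the shared slide). Their median was 0.42 (camera adjusted p = 2.6e-04, 1.4e-04 on the shared slide), and adjusted p = 0.514 with an estimated correlation. Without scaling 6 were higher and 7 lower, the median was 0.07, and the list still passed relative to other genes. IFIT1, an antiviral RNA-binding protein, rose by 1.67, IFI44 by 1.63, BST2, which tethers budding virus, by 1.03 and the signal transducer STAT2 by 0.97. IFIT5 (-0.96) and SAMD9L (-0.48) fell.

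Cytokine and chemokine genes under NF-kB control went down, with 11 of 22 measured genes lower and 3 higher (3 and 11 adjusted over the list alone, 3 and 10 on the shared slide, each given as higher then lower). Their median was -0.35 (camera adjusted p = 0.00915, 0.00604 on the shared slide), and adjusted p = 0.799 with an estimated correlation. Without scaling 0 were higher and 15 lower. After IL6, the falls included PTGS2, the inducible cyclooxygenase, at -2.35, LIF, a cytokine of implantation, at -1.98, and the neutrophil chemokine CXCL2 at -1.17. RELB, an NF-kB subunit, the adhesion molecule ICAM1 and the cytokine IL32 were higher, by 0.57, 0.25 and 0.47. IL32 and ICAM1 lost their calls without control siRNA replicate 2 or any one PRDX2 siRNA array (adjusted p = 0.0806 to 0.108), ICAM1 also without control siRNA replicate 3 (0.0599), and without scaling ICAM1 was at -0.10. Among immediate early genes 9 rose and 13 fell of 33 measured (11 and 14 adjusted over the list alone, 9 and 16 on the shared slide, camera adjusted p = 0.228). The transcription factor genes JUN, KLF6 and MYC changed by -1.82, -1.80 and -1.49, and the nuclear receptor gene NR4A2 rose by 1.75.

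Histone genes fell and had the lowest median of the lists, with 13 of 16 measured genes lower and 0 higher (0 and 14 adjusted over the list alone, 0 and 13 on the shared slide, each given as higher then lower). Their median was -1.04 and -1.05 on the shared slide (camera adjusted p = 2.5e-06 and 2.5e-06), and adjusted p = 0.799 with an estimated correlation, and without scaling 0 were higher and 15 lower. H2BC12 changed by -1.47, H2BC14 by -1.18, H2AC17 by -1.09 and H2BC5 by -0.81. Genes of the G1/S transition and DNA replication fell as well, 14 lower and 2 higher of 40 measured (2 and 14 adjusted over the list alone, 3 and 13 on the shared slide, higher then lower, with 7 lower without PRDX2 siRNA replicate 1 and 9 without PRDX2 siRNA replicate 2 or control siRNA replicate 3). Their median was -0.21 (camera adjusted p = 0.00408, 0.0149 on the shared slide), and adjusted p = 0.714 with an estimated correlation, and without scaling 0 were higher and 31 lower. POLA1, a subunit of DNA polymerase alpha, changed by -0.67, the chromatin regulator UHRF1 by -0.87 and the transcription factor E2F2 by -0.62. The brightest probe of RRM2, a ribonucleotide reductase subunit, changed by -0.88, while its other probes read 0.56 and 0.95 and did not pass. In the G2/M and mitosis list 9 rose and 8 fell of 40 measured (9 and 8 adjusted over the list alone, 10 and 6 on the shared slide, 7 to 10 and 3 to 6 with single arrays left out, camera adjusted p = 0.921). Among them were the kinetochore motor CENPE at -1.15, cyclin A2, CCNA2, at -0.73, ASPM at -0.78 and NUSAP1 at 0.53.

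Among p53 targets 10 rose and 5 fell of 29 measured (11 and 6 adjusted over the list alone, 11 and 7 on the shared slide, camera adjusted p = 0.54). AEN, an apoptosis-enhancing nuclease, changed by -1.17, GADD45A by -1.36 and the kinase PLK2 by -0.87, and the antiproliferative gene BTG2 rose by 0.94. Of the apoptosis machinery 6 rose and 9 fell of 31 measured (6 and 9 adjusted over the list alone, 7 and 10 on the shared slide, 3 to 7 and 6 to 10 with single arrays left out, camera adjusted p = 0.632). The BH3-only genes BBC3 and BCL2L11, which promote cell death, rose by 1.35 and 0.94, CASP9 rose by 0.59, and CYCS, which encodes cytochrome c, changed by -0.81.

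Targets of YAP and TAZ, the transcriptional co-activators of the Hippo pathway, fell, with 15 of 24 measured genes lower and 2 higher (3 and 17 adjusted over the list alone, 2 and 16 on the shared slide, higher then lower). Their median was -0.41 (camera adjusted p = 4.4e-05, 8.4e-05 on the shared slide), and adjusted p = 0.547 with an estimated correlation, and without scaling 0 were higher and 21 lower. F3, tissue factor, changed by -2.47, FJX1 by -2.01, IGFBP3 by -1.46 and the junction protein AJUBA by -1.40, while RBMS3 rose by 0.53. CCN1 was higher by 0.32, but at -0.0974 with quantile normalization and -0.0277 without scaling, and it lost its call without PRDX2 siRNA replicate 1 (adjusted p = 0.059). Among TGF-beta and SMAD targets 4 rose and 7 fell of 22 measured (5 and 9 adjusted over the list alone, 6 and 7 on the shared slide, camera adjusted p = 0.469), with ID2 at -1.54, SERPINE1 at -1.37, TGFB2 at -1.30 and TGFB3 at -1.14. Among Wnt/beta-catenin targets 2 rose and 4 fell of 13 measured (2 and 5 adjusted over the list alone, 2 and 4 on the shared slide, camera adjusted p = 0.632), with the Wnt antagonist DKK1 at -2.61 against SP5 at 1.51 and AXIN2 at 0.99.

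Genes of invasion and adhesion, functions of the extravillous trophoblast, went both ways. Among matrix metalloproteinases, the plasminogen system and their inhibitors 4 rose and 8 fell of 19 measured (4 and 9 adjusted over the list alone, 4 and 8 on the shared slide, camera adjusted p = 0.228). PLAU, the urokinase gene, changed by -1.46 and the inhibitor TIMP3 by -1.64, whereas the metalloproteinases MMP15 and MMP11 rose by 1.88 and 1.096. Among integrins and adhesion genes 3 rose and 10 fell of 23 measured (3 and 11 adjusted over the list alone, 3 and 10 on the shared slide). That list had camera adjusted p = 0.0544 with all arrays, 0.0778 on the shared slide and 0.0352 without control siRNA replicate 3. It also passed camera with normexp background correction (0.0226), no filter (0.00882) and the stricter filter (0.0474). The same held with trend and robust options (0.0349) and the added 75th percentile (0.0407), and by fry (adjusted p = 6.0e-04). In the other alternatives it did not pass. CD44, the hyaluronan receptor, changed by -1.60 with its other probe at -0.17 and not past the threshold, the gap junction gene GJA1 by -0.91, and CLDN4 and ITGB4 rose by 1.27 and 0.69. Among collagens and matrix proteins 6 rose and 13 fell of 31 measured (8 and 13 adjusted over the list alone, 8 and 13 on the shared slide, camera adjusted p = 0.228), with COL4A6 at -1.86, THBS2 at -1.17, COL12A1 at -1.12 and COL4A2 at 0.77. Among regulators of the epithelial-mesenchymal transition 5 rose and 6 fell of 18 measured (5 and 7 adjusted over the list alone, 5 and 6 on the shared slide, camera adjusted p = 0.84). The related repressors split, with SNAI2 at -2.16, SNAI1 at 1.76 and SNAI3 at least 4.43-fold higher from 0 of 3 control arrays above background, and the epithelial splicing regulator ESRP2 changed by -1.05.

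In metabolism, 6 rose and 9 fell of 27 measured in the glycolysis and lactate list (6 and 9 adjusted over the list alone, 6 and 9 on the shared slide, 5 to 6 and 4 to 9 with single arrays left out, camera adjusted p = 0.84). The pyruvate dehydrogenase kinases PDK4 and PDK1 moved apart, at 1.198 and -0.70, and ALDOC and the glucose transporter SLC2A3 rose by 0.94 and 0.70. Hypoxia (HIF) targets were divided, as 11 rose and 8 fell of 27 measured (12 and 9 adjusted over the list alone, 12 and 8 on the shared slide, camera adjusted p = 0.836). ADM, which encodes adrenomedullin, changed by -2.11 and the co-regulator CITED2 by -2.07, against NDRG1 at 1.61 and MXI1 at 0.78. In the cholesterol synthesis and uptake list 3 rose and 4 fell of 24 measured (3 and 4 adjusted over the list alone, 8 and 4 on the shared slide, camera adjusted p = 0.998), with LSS at -0.70, PMVK at -0.52 and MSMO1 at 0.85. In fatty acid synthesis and desaturation 2 rose and 10 fell of 23 measured (4 and 11 adjusted over the list alone, 4 and 9 on the shared slide, 1 to 4 and 5 to 9 with single arrays left out, camera adjusted p = 0.114). The falls included ELOVL1 at -0.94, LPIN1 at -0.77 and ACSL3 at -0.63. The 2 probes of SREBF1, the lipid synthesis regulator, went opposite ways, at -0.93 and 0.59, and both passed. In autophagy and lysosome genes 8 rose and 7 fell of 34 measured (13 and 7 adjusted over the list alone, 9 and 8 on the shared slide, camera adjusted p = 0.632), with WIPI1 at 1.09, GABARAPL1 at 0.94, CTSB at 0.71 and WIPI2 at 0.67. The other WIPI2 probe read -0.0329 and did not pass. Of the nuclear-encoded respiratory chain 2 rose and 0 fell of 43 measured (0 and 0 adjusted over the list alone, 1 and 1 on the shared slide, camera adjusted p = 0.632). The 2 genes were NDUFB5 at 0.32 and SDHA at 0.22. The other NDUFB5 probe read 0.00665, and the other SDHA probes 0.265, 0.181 and 0.103, none of which passed. Both were below 0 without scaling, and NDUFB5 lost its call without any one array other than PRDX2 siRNA replicate 1 (adjusted p = 0.0616 to 0.103), SDHA without any one other than control siRNA replicate 1 (adjusted p = 0.0715 to 0.118).

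Ribosomal protein genes, among the brightest on the arrays, had 20 of 55 measured genes higher and 0 lower (39 and 0 adjusted over the list alone, 28 and 0 on the shared slide, 5 higher without control siRNA replicate 2 and 4, 3 and 3 without PRDX2 siRNA replicate 1, 2 and 3), with a median of 0.34 and 0.25 on the shared slide (camera adjusted p = 6.3e-07 and 7.6e-08) and adjusted p = 0.799 with an estimated correlation. RPS25 rose by 0.52, RPLP2 by 0.50 and RPL28 by 0.32. The rise was not kept with quantile normalization, where the median was 0.04 and camera's adjusted p was 0.762, or with the value table of the series (0.04 and 0.769). Without scaling the median was -0.01 with 0 genes higher and 0 lower, and the list still passed relative to other genes. Random lists of genes as bright had a median of 0.35. In the small RNA pathway 1 rose and 2 fell of 13 measured (1 and 2 adjusted over the list alone, 2 and 2 on the shared slide, camera adjusted p = 0.632). DGCR8, the microprocessor partner of DROSHA, changed by -1.36 and XPO5, which exports precursor microRNAs, by -0.80. AGO4 rose by 0.33. That value was below 0 without scaling, and the call was lost without any one array other than control siRNA replicate 1 (adjusted p = 0.0543 to 0.0996).

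**Figure D3:**
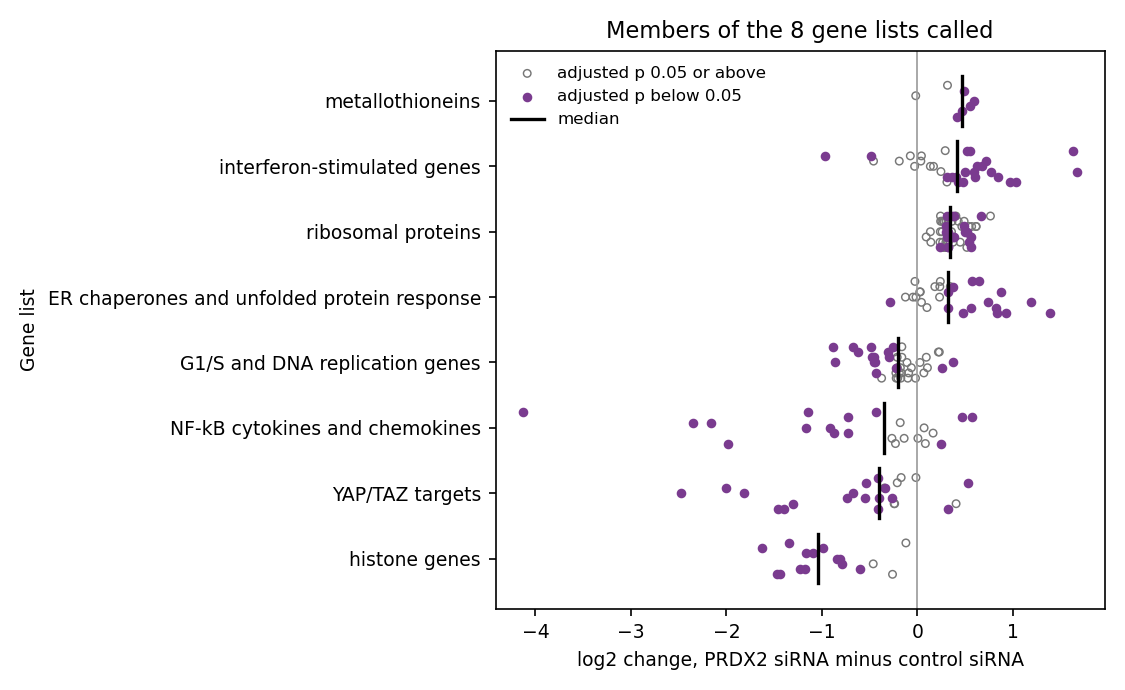
Log2 change of each measured member (dots, PRDX2 siRNA minus control siRNA, x axis) of the 8 gene lists that passed camera (y axis), filled where the gene passed, with a black line at each list's median. None of the 8 passed with an estimated correlation (lowest adjusted p = 0.514). Medians ran from -1.04 for histone genes to 0.47 for metallothioneins. The ribosomal protein median of 0.34 was 0.04 with quantile normalization and -0.01 without scaling, and that of the endoplasmic reticulum chaperones -0.03 without scaling.

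Markers of placental cell types were partly measured. Of the extravillous trophoblast markers 2 rose and 5 fell of 10 measured (2 and 5 adjusted over the list alone, 2 and 5 on the shared slide, camera adjusted p = 0.185). PAPPA, a protease that releases insulin-like growth factors, changed by -2.95, PLAC8 by -0.94 and FSTL3 by -0.82, and HLA-G, the class I molecule typical of these cells, rose by 0.36. Of villous cytotrophoblast markers 2 rose and 4 fell of 12 measured (2 and 4 adjusted over the list alone, 2 and 4 on the shared slide, camera adjusted p = 0.641), with the transcription factor genes GATA3 and GATA2 at -0.92 and 0.48, ITGA6 at -0.63 and LRP5 at 0.61. Of syncytiotrophoblast markers 2 rose and 4 fell of 12 measured (2 and 4 adjusted over the list alone, 1 and 4 on the shared slide, camera adjusted p = 0.404). The pregnancy-specific glycoprotein genes PSG1, PSG2 and PSG5 changed by -1.96, -1.75 and -1.46, while HSD11B2, which inactivates cortisol, rose by 1.25. Of markers of other cells, 5 rose and 3 fell of 15 measured in the stromal and mesenchymal list (5 and 3 adjusted over the list alone, 5 and 2 on the shared slide, camera adjusted p = 0.709), with VIM at 0.54, TAGLN at 0.62, TWIST1 at 0.53 and NT5E at -0.68 (its other probe at -2.22). In the endothelial list 1 rose and 1 fell of 5 measured (2 and 1 adjusted over the list alone, 1 and 1 on the shared slide, camera adjusted p = 0.828), with TIE1 at 1.05 and ROBO4 at -2.43. In the immune list 1 rose and 0 fell of 6 measured (0 and 0 adjusted over the list alone, 1 and 0 on the shared slide, camera adjusted p = 0.54). The gene was CD3E at 1.102, above background on 1 of 3 control arrays, and it did not pass without control siRNA replicate 3 or any one PRDX2 siRNA array (adjusted p = 0.0619 to 0.105).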

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

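The 75th percentile over probes above background on all 6 arrays and the removal of the probe GC trend were chosen after the data were seen. The fall of PRDX2 passed in all 22 alternatives, and it ranged from -0.96 to -0.87 when single arrays were left out. The count of changed genes stayed within 1.5 times of 7800 in 20 of 22 alternatives. It was 4714 with no filter on dim probes, where more features were tested, and 3513 with treat against a 1.2-fold change, which asks for a larger effect. Leaving out single arrays gave 5426 to 8501 genes and 7 to 9 lists. The balance of directions moved with the scaling and with the background correction. Without scaling, 1152 genes were higher and 8413 lower, with normexp background correction 5933 and 4427, and with the 75th percentile over probes above background on all 6 arrays 5030 and 3395. The cause was not tested. The count of lists was 15 with no filter, 0 with an estimated correlation and 21 with fry. Of the 8 lists called, 6 kept their call in 22 of 23 alternatives, all but the estimated correlation. Ribosomal proteins kept it in 20, and metallothioneins in 10. The slide as a block and the fit without control siRNA replicate 1, alone on its slide, are the same fit. Each of these counts therefore includes that fit more than once. Quantile normalization and the value table of the series were also close, with 7916 and 7901 changed genes. Lists were not run with treat, since camera takes no fold threshold. With the replicate block, the replicate number as a factor beside group, 6987 genes and 7 lists passed, and PRDX2 stood at -0.91 (adjusted p = 0.00831). Residuals of samples with the same number correlated at 0.13, 0.09 and 0.03, and those of other pairs at -0.11 to 0.05. Control replicates 1 and 2 correlated best with the PRDX2 siRNA array of the same number. Control replicate 3 correlated best with PRDX2 siRNA replicate 2, at 0.05. The labels do not say whether equal numbers mark the same experiment.

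Of 165 named genes that passed, 127 kept their call and direction in all alternatives, 38 lost the call in some, and 11 of their values changed sign. RPS3A, whose 5 other probes did not pass (-0.0275 to 0.482), was at -0.0446 with quantile normalization and -0.0417 with the value table of the series, and it lost its call without control siRNA replicate 2 (adjusted p = 0.0515), PRDX2 siRNA replicate 2 (0.0599) or PRDX2 siRNA replicate 3 (0.0553). Without scaling, NDUFB5 was at -0.0288, SDHA at -0.13, RPL28 at -0.0260, AGO4 at -0.0190, ICAM1 at -0.10 and CCN1 at -0.0277. There the median of all genes was -0.29. CCN1 was also at -0.0974 with quantile normalization and -0.0948 with the value table of the series. RRM2 was at 0.21 with the mean of its probes, because its dimmer probes read above 0. Signal over background limits the bounds given for genes absent from one group.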

Other observations

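The family counts, the genes named in the next 2 paragraphs and the tests of slide, seed word and splits of the arrays were chosen after the results were seen. Genes, those of the fixed lists included, were also grouped by the stem of their symbol into 172 families of at least 10 measured members. The families had 344 one-sided Fisher tests adjusted together. These tests count genes as independent, so their p-values are too small where a family's genes vary together. The fixed histone list, part of the histone family here, had adjusted p = 0.799 by camera with an estimated correlation. Of 77 measured histone genes H1 to H4, 54 fell and 1 rose (median -0.91, adjusted p = 6.2e-16). DEAD-box helicase genes (DDX), which remodel RNA, had 20 of 38 lower and 3 higher (median -0.34, adjusted p = 0.0116), and tRNA methyltransferase genes (TRMT) had 10 of 15 lower and 1 higher (median -0.42, adjusted p = 0.033). Golgin genes (GOLGA), several of them near-identical copies, had 11 of 19 higher and 1 lower (median 0.39, adjusted p = 0.0199).

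HSPA6, HSPA1B, DNAJB1, BAG3 and HMOX1 were highest on PRDX2 siRNA replicate 2, while HSPA2, HSPA4L and HSP90AA1 were not. HSPA1B stood at 6.62 there, against 4.24 and 4.84 on the other PRDX2 siRNA arrays and 1.44 to 1.83 on control arrays. DNAJB1, BAG3 and HMOX1 did not pass with all arrays (1.25, 0.79 and 1.58, limma adjusted p = 0.0579, 0.0875 and 0.0802). All of them passed without PRDX2 siRNA replicate 2, at smaller values of 0.78, 0.43 and 0.88 (adjusted p = 0.0423, 0.0284 and 0.0244), and with normexp background correction or array weights. DNAJB1 also passed without PRDX2 siRNA replicate 1 (1.57, adjusted p = 0.0439). TXNIP was lowest on PRDX2 siRNA replicate 2, at 2.88 against 4.22 and 3.83. Of the arrestin-domain relatives of TXNIP, ARRDC4 fell by 4.70, while ARRDC2 and ARRDC3 had values of 0.11 and -0.00453 and did not pass. Besides PSG1, PSG2 and PSG5, the pregnancy-specific glycoprotein genes PSG3, PSG6 and PSG8 changed by -1.20, -2.42 and -1.70, and PSG9 had -0.21 and did not pass by its brightest probe, while its other probe passed as lower, with 0 of 3 PRDX2 siRNA arrays above background. Without scaling PSG9 passed as lower, at -0.56. Whether the probes of these related genes share signal was not tested, so the falls may not be independent.

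Ribosomal protein genes rose together in the values scaled by the 75th percentile. Removal of the probe GC trend left their median at 0.32, and the shared slide left it at 0.25, both past camera's threshold, which argues against either as the whole cause. Signal level remains: 50.5% of 10000 random lists matched on mean signal had a median as high, and 35.9% did with the other ribosomal protein genes kept out of the random lists. The rise may therefore belong to probes as bright as these and not to these genes. The brightest 2038 genes as a whole had a median of 0.05, against 0.06 for all genes. That group is broader than the matched lists, which had a median of 0.35. It therefore does not show that probes as bright as these stayed level. No biological explanation was tested.

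Histone genes fell together. None of the technical explanations tested accounts for the fall as a whole: the median was -1.16 with the probe GC trend removed and -1.05 on the shared slide, and 0% of 10000 random lists matched on mean signal had a median as low. No biological explanation was tested, nor was signal shared between the near-identical copies of histone genes. The members' residuals correlated at 0.63, so the list counts for few independent genes.

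In all, 1110 genes fell further than PRDX2 itself. The slide of control siRNA replicate 1 does not account for this, since 1183 genes did so on the shared slide. An siRNA acting through its seed, as microRNAs do, is a candidate explanation that stays open. Genes whose 60-base probe holds the guide's seed word GTTAATG, 77 in number, had a median of -0.02 against 0.06 in the others, and 21.3% of 9376 words about as common had a median as low (8.52% had a mean as low), while the 20 with the 8-base word GTTAATGA had 0.14, and 73.7% of words as common had a median as low. Of the 77 genes, 19 passed as lower and 11 as higher, and 24.7% were lower against 20.4% of the others. Those lower include IL6 (-4.13), ID2 (-1.54) and PDK1 (-0.70), named above. Probes cover little of a transcript, so most sites went unsearched.

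The 6 arrays can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 7800 genes and 8 lists, and 1 of 10 divisions, the real one, reached each. The highest of the others gave 0 genes by limma with adjusted p below 0.05, at most 551 with an unadjusted p below 0.05 against 9948 for the real groups, and 7 lists. In each of the others both sides hold arrays of both groups, so the real difference adds to the spread within a side. Low gene counts there were built in, and they do not show how many genes would be called without a real difference.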
